A study of Mus musculus with 2 samples.

How the data were processed

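The data are microRNA-seq libraries from the left cerebral cortex of male 5xFAD/CAST mice, 2 libraries in 1 group, with the group and the replicate numbers taken from the labels. Each library has a deposited table of read counts for 2202 microRNA genes, and the unit is raw counts, not normalised. The table was made against the mm10 assembly and the GENCODE M21 annotation, per the notes deposited with the file. The aligner and counter and their settings are not given in the sources used here. The layout of the table, with 3 count columns (without regard to strand, sense and antisense) and 4 lines of unassigned totals, is that of STAR gene counts, which is an inference from the layout. Within each column the gene counts and these 4 totals add up to the same number of reads. Counts are given per precursor gene, so the arms of a precursor are not told apart.

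Unassigned reads stayed out of library sizes and tests. In replicate 1, 25.6% of the reads were unmapped, 38.5% mapped to several places and 5.82% mapped outside microRNA genes, and in replicate 2 these were 34.3%, 33.0% and 6.54%. Reads listed as mapping to several places form a total of their own beside the gene counts, so microRNAs with several identical copies can be undercounted, and their levels are uncertain. Of the 2202 genes, 1087 share a stretch of 20 bases with another annotated microRNA locus. Matches elsewhere in the genome were not searched. Another 2.13% of reads in replicate 1 and 1.88% in replicate 2 were ambiguous in the column without strand, because 64 genes overlap a microRNA gene on the other strand. These genes are counted fully in the sense column, which was therefore used throughout. The reads come from a strain labelled 5xFAD/CAST and were counted against the mm10 reference, and the effect of strain differences on the counts was not measured.

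All gene identifiers in the tables (2202 of 2202) were found in the GENCODE M21 annotation, from which symbols, coordinates (mm10, counted from 1) and host genes were taken. Host genes were searched on the strand of the microRNA gene only. Where several host genes overlapped, a protein-coding gene with an assigned name was preferred. CPM was computed from the sense counts by scaling the reads assigned to microRNA genes in that library to a total of 1000000; these were 4929428 in replicate 1 and 4441328 in replicate 2. A gene was called detected with at least 10 counts in each library. Log2 levels used a pseudocount of 1 CPM, which draws low levels together. The floor for a gene without reads is 3 counts, 0.609 CPM in replicate 1 and 0.675 CPM in replicate 2. Reads carry no molecular identifiers that were used here, so intervals and floors cover counting error only.

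There is no control group, and no comparison between conditions was made. The spread between libraries was fitted as the common dispersion of an intercept-only model in edgeR 4.0.16 (R 4.3.3) with TMM factors, with a bootstrap over genes for its interval. The 2 libraries were compared gene by gene with an exact two-sided binomial test given both library totals, with Benjamini-Hochberg adjustment over the 417 detected genes and a threshold of 0.05; ratios have exact 95% intervals. Before the data were examined, 18 lists of microRNA genes were fixed: neurons, astroglia, oligodendrocytes, microglia and leukocytes, red blood cells, vessels, choroid plexus and ependyma, epithelia, Hox clusters, muscle, liver with gut and pancreas, embryonic stem cells, the X-linked testis cluster, let-7, miR-17~92, Dlk1-Dio3, microRNAs often named in amyloid work, and multi-copy loci. Members of several lists overlap, and many are also made in other cells. Detected genes on the same strand within 10 kb of each other were taken as a cluster. The neuronal list was compared with 5 lists of other cells by permuting list membership (100000 draws, or all arrangements where these were fewer), with Benjamini-Hochberg adjustment over the 5.

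Genes are named by a rule set before the data were examined. It takes the 20 genes with the highest mean CPM, the 5 widest ratios between libraries among genes with at least 100 counts in each, the 3 most abundant members of each list with up to 3 members without reads from lists whose median is at least 100 CPM, and the 3 genes with the most opposite-strand reads. Other genes named were chosen after their values were seen.

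The steps were tested on simulated data. For the spread between the 2 libraries, simulated coefficients of variation of 0.1, 0.4 and 0.8 were recovered as 0.0978, 0.394 and 0.743 over 406, 396 and 365 genes. For the comparison of the libraries, over 419 genes tested, the binomial test called 64.6% of genes simulated at 1.5-fold, 82.5% at 2-fold and 98.2% at 4-fold, and 1.71% of unchanged genes. That simulation holds counting error alone, and its changed genes were drawn from those under 1000 CPM.

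Alternatives were the column without strand, scaling by TMM or by the size factors of DESeq2 1.42.0, other count minimums, a pseudocount of 10 CPM, each library alone, list members outside the multi-copy loci, and a total without the most abundant gene. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 was used.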

Results

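MicroRNA-seq, which sequences RNA shorter than 30 bases, was carried out on total RNA of the left cerebral cortex of adult male mice of the strain 5xFAD/CAST, aged 8 to 10 months. 5xFAD is a transgenic mouse model of amyloid deposition, and CAST is the usual short name of an inbred strain derived from wild mice. The labels do not say whether the animals sampled carried the transgenes. The data are 2 libraries, named in the labels as biological replicates 1 and 2 of 1 group. They come from separate tissue samples that carry the same donor identifier, so the spread between them may be technical, or may be that between animals. No control mice were analysed here, and the results are therefore levels of microRNAs in this cortex and their spread between the 2 libraries. Replicate 1 held 16403925 reads, of which 4929428 (30.1%) were assigned to microRNA genes on the sense strand, and replicate 2 held 16991914 reads, of which 4441328 (26.1%) were assigned. Levels are counts scaled to a library total of 1000000 (CPM), and a single read corresponds to 0.203 CPM in replicate 1 and to 0.225 CPM in replicate 2. Values with an error are the mean ± SD of the 2 libraries (n = 2).

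The gene counts were dominated by few microRNAs. The highest count was that of Mir139 at 126656 ± 10647 CPM, ahead of Mirlet7g at 106077 ± 8270 CPM and Mirlet7b at 69806 ± 1176 CPM. Mir139 was above Mirlet7g in both libraries, at 134185 against 100229 CPM in replicate 1 and at 119128 against 111925 CPM in replicate 2. This order and the shares of reads hold for reads assigned to a gene; reads that mapped to several places, 1.28 and 1.26 for each assigned read in replicates 1 and 2, are not in the gene counts. The 10 most abundant genes took 57.2 ± 1.35% of the assigned microRNA reads, the first 20 took 69.7 ± 0.149% and the first 50 took 87.5 ± 0.0116%. The first 10 and the first 50 were ranked within each library, and the first 20 by the mean CPM of both. Of the 2202 annotated microRNA genes, 417 (18.9%) had at least 10 reads in each library and are called detected, 96 reached a mean of 1000 CPM, and 1436 had no read in either library. A gene with no read could still have been present at up to 0.609 CPM in replicate 1 and 0.675 CPM in replicate 2, the level of 3 reads, and these limits cover counting error only.

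Several of the leading microRNAs lie inside protein-coding genes (GENCODE M21 annotation of mm10). Mir139 is at chromosome 7, 101475376 to 101475443 on the plus strand, in an intron of Pde2a, which encodes a phosphodiesterase that degrades cyclic nucleotides. Mirlet7g is at chromosome 9, 106178840 to 106178927, in an intron of Wdr82. Mir744, at 58345 ± 13748 CPM, is at chromosome 11, 65734733 to 65734832 on the minus strand, in an intron of the kinase gene Map2k4. Mir126a, at 13972 ± 1189 CPM, overlaps an annotated exon of the endothelial gene Egfl7 at chromosome 2, 26591357 to 26591429. An exon of any annotated transcript counted for this, so Mir126a may lie in an intron of other Egfl7 transcripts. Introns also held Mir151 in Ptk2 (11978 ± 194 CPM), Mir652 in Tmem164 (11777 ± 221.6 CPM), Mir128-1 in R3hdm1 (10524 ± 4287 CPM) and Mir26b in Ctdsp1 (10324 ± 3759 CPM). Mir99a (22196 ± 9119 CPM) lay in an intron of the long non-coding RNA Mir99ahg. For Mir328 (12036 ± 299 CPM) and Mir23a (11380 ± 4791 CPM) no host gene was found on the same strand, and the opposite strand was not searched. Of the 20 most abundant genes, only Mir132 differed at least 2-fold between the libraries, and the median coefficient of variation over the 20 was 8.10%.

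**Figure D1:**
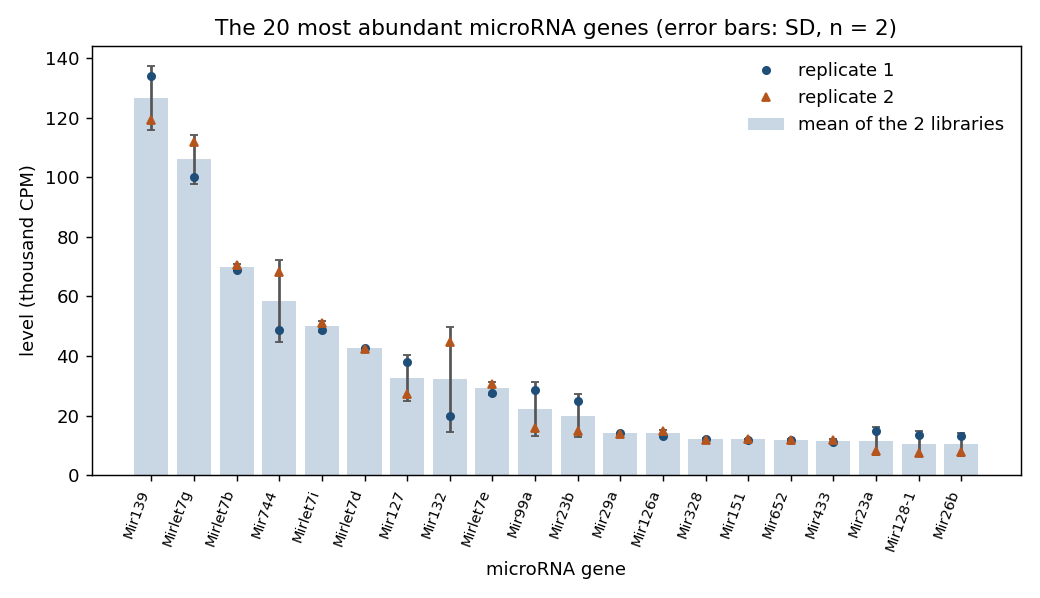
Levels of the 20 most abundant microRNA genes in units of 1000 CPM. Bars are means of the 2 libraries from 0, error bars are SD (n = 2), and points are the single libraries; Mir139 leads at 126656 CPM and Mir132 has the widest gap between its points.

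The let-7 family, regulators that promote the differentiated state of cells and repress growth genes, was the most abundant of the families and loci examined. All 12 of its annotated members were detected, and together they took 30.9 ± 1.51% of the microRNA reads. Most of this came from Mirlet7g, Mirlet7b, Mirlet7i (49958 ± 1762 CPM), Mirlet7d (42584 ± 152 CPM) and Mirlet7e (29123 ± 2260 CPM), each of which is made from a single locus. Members made from several loci were far lower: Mirlet7f-2 stood at 4112 ± 556 CPM, and Mirlet7a-1, Mirlet7a-2, Mirlet7c-1 and Mirlet7f-1 lay between 278 and 556 CPM, with Mirlet7c-2 at 1416 ± 104 CPM. Mir98, a single-copy member, was at 4081 ± 1340 CPM. Reads that matched several places in the genome are kept in a separate total and are not in the gene counts, which can lower the counts of members that share their mature sequence with another locus. The median of the family, as log2(CPM + 1), was 11.98 ± 0.34, and it was 15.49 over the members outside the list of multi-copy loci.

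Most microRNAs of the neuronal list were detected. Of the 25 annotated members of the list for neurons, 22 were detected, and the list took 7.01 ± 0.681% of the reads. Its most abundant member was Mir132, whose transcription follows neuronal activity, at 32190 ± 17689 CPM, followed by Mir128-1 and by Mir137 at 9344 ± 4234 CPM. Mir124, the best known neuronal microRNA, is made from 3 loci and was almost absent from the counts: Mir124a-1 had 21 and 12 reads, Mir124a-2 had 9 and 7, and Mir124a-3 had 3 and 0. Mir9, also made from 3 loci, reached 97.0 ± 12.9 CPM at Mir9-3. Each of these loci shares a stretch of 20 bases with at least 2 other places in the genome, and reads counted as matching several places are not in the gene counts. Mir873b had no read in either library.

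MicroRNAs of glia and vessels were led by a few abundant genes. The astroglial list, made of the miR-29 family, the cluster of Mir23b, Mir27b and Mir24-1, and Mir31, had 8 of 8 members detected and took 3.80 ± 0.565% of the reads, mostly as Mir23b (19973 ± 7163 CPM) and Mir29a (14018 ± 158 CPM), with Mir29c at 1528 ± 286 CPM. The vascular list took 2.11 ± 0.0986%, with 3 of 5 members detected: the endothelial Mir126a, and Mir143 (6869 ± 224 CPM) and Mir145a (273 ± 20.9 CPM), which are made in smooth muscle and pericytes. Mir126b and Mir145b had no read. The oligodendrocyte list took 0.452 ± 0.157%, with 4 of 7 members detected. It was led by Mir338 (2720 ± 561 CPM) and Mir219a-2 (1783 ± 1016 CPM), which act in oligodendrocyte maturation, ahead of Mir32 (14.3 ± 3.63 CPM). Mir219a-2 shares a stretch of 20 bases with 2 other annotated microRNA loci, so its count may miss reads that mapped to several places.

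Blood and immune microRNAs were low. The microglia and leukocyte list took 0.201 ± 0.0104% of the reads with 5 of 7 members detected, led by Mir150 (973 ± 141 CPM), a lymphocyte microRNA, Mir146 (773 ± 249 CPM), induced in inflammatory signalling, and Mir142 (139 ± 9.75 CPM), made in blood-forming cells and their progeny, while Mir142b had no read. Mir155 was at 112 ± 17.1 CPM and the myeloid Mir223 at 10.1 ± 1.04 CPM. The erythroid list took 0.0345 ± 0.0363%, with 3 of 4 annotated members detected, and it differed widely between the libraries: Mir451a, the main microRNA of red blood cells, stood at 529 CPM in replicate 1 and at 52.2 CPM in replicate 2, and its neighbour Mir144 at 57.8 and 6.30 CPM. Mir486 stood at 15.0 and 29.9 CPM. Its precursor holds a self-complementary stretch of 20 bases, so that a read from it can match both strands.

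The mean level of the neuronal list, as log2(CPM + 1), was 3.34 above that of the oligodendrocyte list (adjusted p = 0.308), 2.21 above the microglia and leukocyte list (adjusted p = 0.375), 0.66 above the vascular list (adjusted p = 0.778) and below the astroglial list by a difference of -1.75 (adjusted p = 0.375), each in a two-sided permutation test of list membership. Against the erythroid list it was 3.52 higher (adjusted p = 0.308, exact permutation test, two-sided). None of the 5 comparisons passed the threshold of 0.05 after Benjamini-Hochberg adjustment, and at an unadjusted p under 0.05 there was also none, since the lowest was 0.0815 in the permutation test against oligodendrocytes. The tests run across genes, which are not independent replicates. The sign of the difference to the vascular list turned with a pseudocount of 10 CPM in place of 1, to -0.14. Over members outside the multi-copy loci the differences were 5.25 to oligodendrocytes, 1.61 to vessels and -3.03 to astroglia, and in the counts without regard to strand they were 6.29 to oligodendrocytes (adjusted p = 0.0092, permutation test), 2.48 to vessels and 5.75 to the erythroid list; of these, only the 6.29 passed the threshold.

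**Figure D2:**
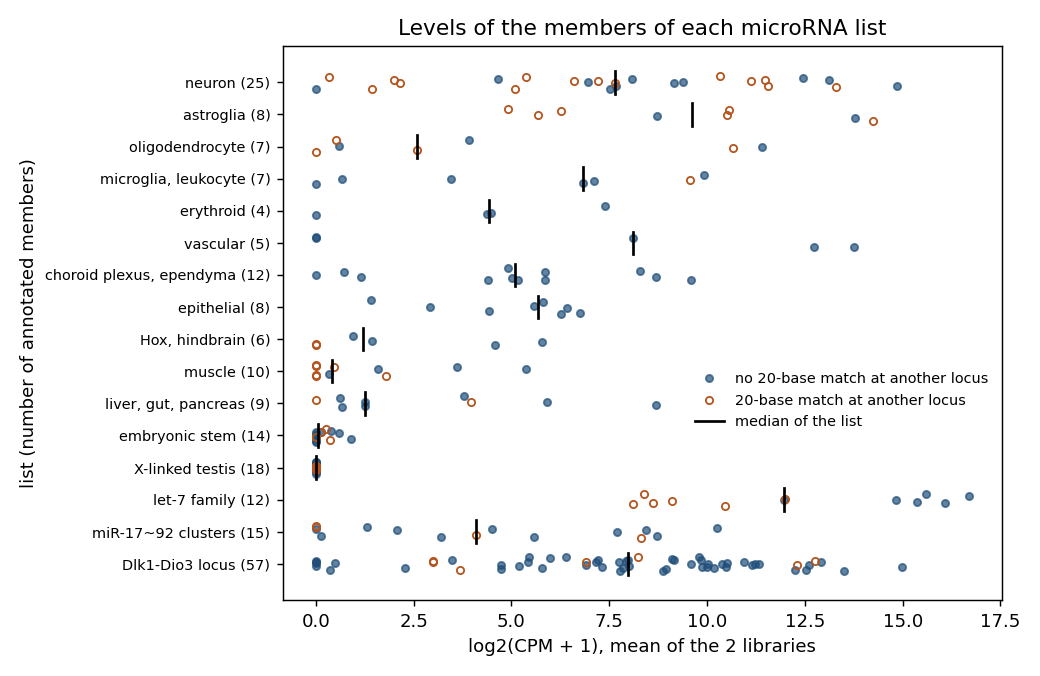
Level of each annotated member of 16 microRNA lists as log2(CPM + 1), mean of the 2 libraries, with list medians as vertical lines. Filled points have no stretch of 20 bases in common with another annotated microRNA locus and open points do. Matches elsewhere in the genome were not searched. The medians run from 0 for the X-linked testis list to 11.98 for the let-7 family.

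The imprinted Dlk1-Dio3 locus on chromosome 12, whose microRNAs are made from the maternal allele and are abundant in brain, supplied 10.7 ± 0.552% of the microRNA reads. Of its 57 annotated members on the list, 50 were detected. The most abundant was Mir127 (32671 ± 7688 CPM, 109592846 to 109592915), followed by Mir433 (11579 ± 506 CPM, 109591715 to 109591838) and Mir770 (7862 ± 2309 CPM, 109563692 to 109563785, within Meg3). Mir3071, Mir453 and Mir654 had no read in either library. The proximal cluster of 13 members from Mir770 onwards took 5.79 ± 0.531% of the reads, and the distal cluster of 34 members from Mir379 onwards took 4.51 ± 0.176%. The miR-17~92 cluster and its paralogues, known for their role in proliferating cells, took 0.263 ± 0.0321%, with 10 of 15 members detected, led by Mir93 (1228 ± 147 CPM), Mir17 (424 ± 1.22 CPM) and Mir106b (347 ± 46.0 CPM).

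MicroRNAs of other tissues and of the lining of the ventricles took small shares of the reads. The list for choroid plexus and ependyma had 9 of 12 members detected and took 0.190 ± 0.0357% of the reads, with Mir204 at 818 ± 376 CPM, Mir34c at 477 ± 331 CPM and Mir1298, in an intron of the serotonin receptor gene Htr2c, at 369 ± 278 CPM. The epithelial list took 0.0413 ± 0.00826%, with 7 of 8 detected and no member above Mir429 at 107.2 ± 2.52 CPM, ahead of Mir183 (84.9 ± 10.2 CPM) and Mir200b (82.7 ± 46.9 CPM). In the list for liver, gut and pancreas, 4 of 9 were detected (0.0511 ± 0.00902% of the reads), namely Mir375 (419 ± 82.9 CPM), the liver microRNA Mir122 (59.9 ± 12.8 CPM), Mir194-2 (14.9 ± 4.72 CPM) and Mir192 (12.8 ± 0.946 CPM). The Hox cluster list, of hindbrain, spinal cord and trunk, took 0.00813 ± 0.00166%, with Mir10a (55.7 ± 20.8 CPM) and Mir10b (23.0 ± 3.50 CPM) as its 2 detected members of 6, and Mir196b had 8 reads in each library. The muscle list took 0.00573 ± 0.000362%, with Mir206 (40.7 ± 7.38 CPM) and Mir499 (11.3 ± 2.64 CPM) as its 2 detected members of 10, ahead of Mir1b (2.52 ± 1.02 CPM). No member of the 14 in the embryonic stem cell list was detected, the highest being Mir302d with 7 and 2 reads, followed by Mir292 with 1 and 4 and Mir291b with 0 and 3. All 18 members of the X-linked testis list, among them Mir465, Mir470 and Mir463, had no read in either library. Mir465, Mir291b, Mir194-2 and Mir1b each share a stretch of 20 bases with another locus. Their counts may miss reads that mapped to several places.

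A list of 22 loci often named in work on amyloid disease was examined for levels alone, since no control mice were analysed here. All 22 were detected, and they took 7.13 ± 2.00% of the reads, led by Mir132, Mir29a and Mir328. The share was 5.71% in replicate 1 and 8.55% in replicate 2, and most of that gap lay in Mir132, which stood at 19682 CPM in replicate 1 and at 44698 CPM in replicate 2. Other members that differed at least 2-fold were Mir298 (log2 ratio of replicate 2 to replicate 1 of 2.17), Mir107 (1.81), Mir29b-1 (1.23), Mir34a (1.06) and Mir101a (-1.60). These were named after their values were seen. Mir29b-1 is a multi-copy locus, and reads that mapped to several places are not in its count, so its ratio may not be that of the mature microRNA. The list of 60 loci whose mature microRNA has several copies took 3.49 ± 0.477% of the reads with 46 detected, led by Mir128-1, Mirlet7f-2 and Mir138-1 (3033 ± 112 CPM).

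The 2 libraries ranked the microRNAs alike but differed by more than counting error. Across the 417 detected genes, which are not independent replicates, log2(CPM + 1) gave a Spearman rho of 0.977 and a Pearson r of 0.980, 9 of the 10 most abundant genes were shared, and the median gene was 1.29-fold apart. The biological coefficient of variation fitted by edgeR was 0.340 (bootstrap over genes, 95% interval 0.296 to 0.388). By an exact two-sided binomial test per gene with Benjamini-Hochberg adjustment, 247 of 417 genes differed (103 higher and 144 lower in replicate 2), and 47 of them differed at least 2-fold (27 higher, 20 lower). This test compares these 2 libraries and not conditions. The counts differed by far more than sampling noise (chi-square per degree of freedom of 634), so the libraries are not a single library deposited again.

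The widest gaps among genes with at least 100 reads in each library were in Mir301, Mir31, Mir451a, Mir26a-1 and Mir153. Mir301, in an intron of Ska2, had 3044 reads in replicate 1 and 104 in replicate 2, a log2 ratio of -4.72 (exact 95% interval -5.02 to -4.44). Mir31 was higher in replicate 2, with 568 and 6890 reads and a log2 ratio of 3.75 (3.63 to 3.88). Mir451a had 2610 and 232 reads (-3.34, interval -3.54 to -3.15), Mir26a-1, in an intron of Ctdspl, had 136 and 886 (2.85, interval 2.59 to 3.13), and Mir153, in an intron of Ptprn2, had 8099 and 1206 (-2.60, interval -2.69 to -2.51). Mir26a-1 is a multi-copy locus, and reads that mapped to several places are not in its count. Its ratio may therefore not be that of the mature microRNA. Mir132 was higher in replicate 2 by a log2 ratio of 1.18 (1.17 to 1.19).

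By list, the neuronal microRNAs were lower in replicate 2 at 14 of the 22 detected members, higher at 5 and not past the threshold at 3. The list's share of the reads was 6.53% in replicate 1 and 7.49% in replicate 2. Mir132 alone took 1.97% and 4.47%, a wider rise than that of the list, so the other members together took a smaller share in replicate 2. Members of the Dlk1-Dio3 locus were lower at 27 of 50, higher at 11 and not past the threshold at 12. The let-7 family was higher at 8 of 12 and lower at 3, with no member 2-fold apart. Adjusted over the list alone, the same numbers passed, 19 for neurons, 38 for the locus and 11 for let-7. Under scaling by TMM factors the lower and higher members were 13 and 5 for neurons, 25 and 14 for the locus, and 3 and 9 for let-7. Of the shorter lists, the astroglial one had 4 members higher and 2 lower, the choroid plexus list 2 and 5, the epithelial list 1 and 5, the miR-17~92 list 0 and 4, and the list from amyloid work 9 and 11; under TMM factors these became 5 and 1, 2 and 5, 1 and 4, 0 and 4, and 10 and 9.

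**Figure D3:**
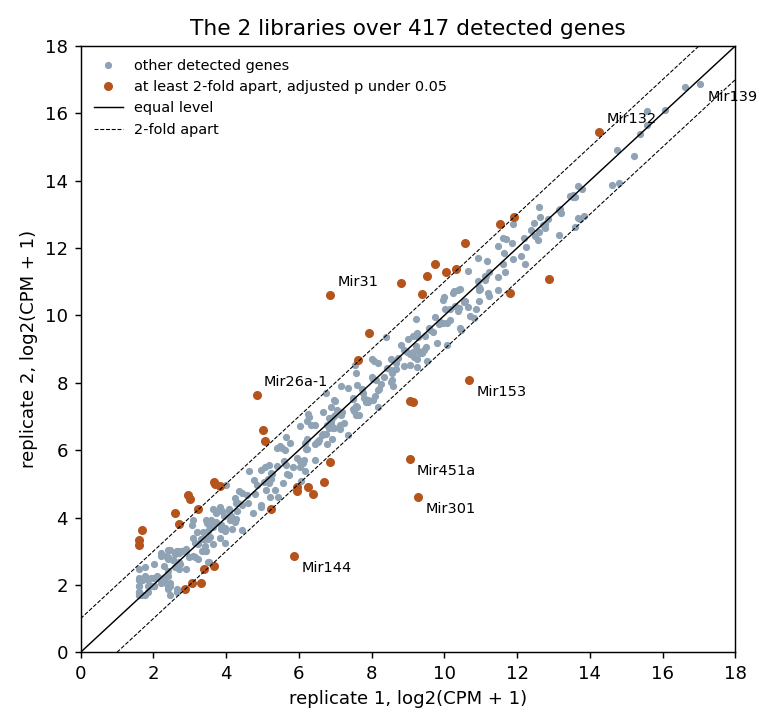
Level of each of the 417 detected genes in replicate 1 (horizontal) and replicate 2 (vertical), as log2(CPM + 1). The solid line marks equal levels, dashed lines mark 2-fold gaps, and the 47 genes at least 2-fold apart that pass the exact binomial test are in orange.

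Counts on the strand opposite to the annotated genes came to 6.62% of the sum of sense and opposite-strand counts in replicate 1. In replicate 2 they came to 6.70%. Nearly all of them (99.9% in each library) sat at genes that overlap another microRNA gene on the other strand. Those counts, 349505 and 318888, equal the reads that were ambiguous in the column without strand. Such reads enter the sum once as sense of a gene and again as opposite-strand of its partner. The shares are therefore not a measure of antisense reads. The 3 genes with the most opposite-strand reads were Gm25927, which overlaps Mirlet7e, Mir126b, which overlaps Mir126a, and Gm24083, which overlaps Mir191. Each had no read on its own strand. Gm25927 held 135683 opposite-strand reads in replicate 1, the same number as the sense count of Mirlet7e.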

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

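The tests of shared copies, of common shifts, of family pairs, of cluster pairs and of blood in this part were chosen after the results were seen; those of TMM and size factor scaling and of GC content were chosen before. The demand that a relation between pairs hold without let-7 or the Dlk1-Dio3 locus was also set after. On the strand opposite to the microRNA genes there were 349685 reads in replicate 1 and 319054 in replicate 2. Of these, 349505 and 318888 sat at genes that overlap a microRNA gene on the other strand. The same numbers of reads were ambiguous in the column without strand, so these reads are already in the sense counts of the overlapping genes. Reads outside the gene counts exceeded the limit for a count of 0, as nearly any total over a library would. Mapped reads outside microRNA genes numbered 955478 and 1112036. Reads that mapped to several places numbered 6320188 and 5615203, which is 1.28 and 1.26 for each read assigned to a gene.

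A first pattern is the low count at microRNAs with several copies, such as the 21 and 12 reads of Mir124a-1. In 9 of 10 seed families the multi-copy loci lay below the single-copy members, by a mean log2 difference of -4.05 ± 2.73 (SD over 10 families; exact two-sided sign-flip test over 1024 arrangements, p = 0.00391). The exception was the miR-25/92 family, at 0.40. Reads that mapped to several places are outside the gene counts, so these low counts do not show that the mature microRNAs were low in the cortex. Reads left out because identical copies share them are a candidate explanation for the gap. A lower true level of the multi-copy members would give the same sign, and how much it adds was not measured and stays open. No biological explanation was tested for this pattern, since the design names none.

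A second pattern is the 47 genes at least 2-fold apart between the libraries. The tables argue against scaling, since 50 genes were at least 2-fold apart under TMM and 50 under size factors, 45 of the 47 among them under each. The gaps run both ways, so a common shift of all log2 ratios that narrows some widens others: over 81 shifts between -2 and 2 the number of genes at least 2-fold apart was lowest, at 47, with no shift, while of the 47 themselves 21 to 47 were still that far apart. Precursor GC content was tested on the 270 genes with at least 100 counts in each library, of which 29 were at least 2-fold apart. For these genes the tables argue against it, with a Spearman rho of 0.0355 (permutation p = 0.549). At so low a rho a linear GC correction could change little, and 30 genes were that far apart after it. The GC content of the mature sequences was not tested. Family members at separate loci lay closer in log2 ratio than random pairs, by -0.24 (one-sided permutation p = 0.0233), but without let-7 by -0.03 (p = 0.451, permutation); clustered genes of different families lay closer by -0.24 (one-sided permutation p = 0.0158), but without the Dlk1-Dio3 locus by -0.03 (p = 0.438, permutation). For these pairs the family was read from the number in the gene name, so Mir98 was not counted with let-7. Related microRNAs with different numbers were thus taken as different families. Capture that depends on the mature sequence and a difference between the tissue samples in transcription of whole clusters cannot be told apart, because each relation rests on a single family or locus. Preparation of the libraries and other differences between the tissue samples stay open and untested.

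The last pattern is the lower Mir451a and Mir144 in replicate 2, with log2 ratios of -3.34 and -3.20. More whole blood in the tissue of replicate 1 may account for it. Mir223 of leukocytes and platelets had a log2 ratio of 0.21 from 46 and 48 reads, which did not pass the exact binomial test (adjusted p = 0.643). That leaves blood open, since the share of Mir223 that is not from blood was not measured, and Mir486, at a log2 ratio of 1.00, has a self-complementary sequence whose reads may be missing from the gene count. No other difference between the tissue samples was tested as its cause, since the design names none.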

How the results depend on the processing

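Of the 144 alternatives to results other than single-gene levels, 111 left the result on its side of the threshold or within its spread. Part of these outcomes were fixed in advance, so this number does not measure how stable the results are. With 2 libraries, the share of the leading genes in either library always lies within the SD, and list medians mostly do. The opposite-strand share was set as unchanged, and Spearman rho cannot change with scaling. All alternatives were chosen before the data were examined. The detected genes numbered 312 to 531, the fitted coefficient of variation lay between 0.334 and 0.376, and the genes that differed between libraries numbered 218 to 275. Scaling moved the median log2 ratio of detected genes from -0.05 to 0.00 and the split of higher and lower genes from 103 and 144 to 118 and 130 (TMM) or 116 and 131 (size factors). No paired analysis was possible because the series has 1 group.

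In the column without strand, genes that overlap a microRNA gene on the other strand lose their reads by construction. The 10 leading genes then took 60.3% of the reads, and list medians as log2(CPM + 1) became 7.33 for neurons, 0 for oligodendrocytes, red blood cells, muscle and embryonic stem cells, 3.56 for microglia and leukocytes, 0.85 for vessels, 11.32 for let-7, 7.32 for Dlk1-Dio3 and 4.34 for multi-copy loci. The neuronal list then lay 6.29 above the oligodendrocyte list (adjusted p = 0.0092, permutation), past the threshold, because Mir338 and Mir219a-2 lose their reads there. Over the other 34 list comparisons none passed, and adjusted p over all 35 ran from 0.0092 to 0.939. With a pseudocount of 10 CPM the neuronal list lay below the vascular one, at -0.14. A larger pseudocount raises members without reads the most. Such members were 2 of 5 in the vascular list and 1 of 25 in the neuronal list. The sign of this difference thus depends on how members without reads are scored.

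With no count minimum, Spearman rho was 0.928, Pearson r 0.984 and 78 genes were at least 2-fold apart; with a minimum of 100 counts these were 0.955, 0.963 and 29, with fewer genes tested. Without Mir139 in the total, the next 10 genes took 53.0%. Members outside the multi-copy loci gave medians of 8.09 for neurons, 0.60 for oligodendrocytes, 3.01 for Hox clusters, 1.69 for muscle, 15.49 for let-7, 4.52 for miR-17~92 and 10.17 for the list from amyloid work; the oligodendrocyte list then lacks Mir219a-1 and Mir219a-2. From each library alone, medians ran from 8.56 (replicate 1) to 10.67 (replicate 2) for astroglia, from 3.91 to 4.94 for red blood cells, from 5.28 to 5.86 for epithelia, from 1.49 to 1.78 for liver, gut and pancreas, from 5.02 to 5.32 for choroid plexus and from 7.92 to 8.18 for Dlk1-Dio3, and were 0 in each for embryonic stem cells. Depth limits genes near 3 reads, about 0.609 to 0.675 CPM.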

Other observations

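Several further microRNAs were abundant or differed between the libraries. Some of them, such as Mir107, are also on the lists. Apart from genes that the naming rule took, such as Mir99a, they were chosen after their values were seen. The miR-99/100 family, of 3 genes, took 3.42 ± 1.55% of the reads (n = 2), and each member was lower in replicate 2: Mir99a at a log2 ratio of -0.86, Mir100 (7233 ± 2596 CPM) at -0.75 and Mir99b (4811 ± 3745 CPM) at -1.79. Mir99b lies in a cluster with Mirlet7e and Mir125a on chromosome 17, where the ratios of its neighbours were 0.16 and -0.01, so that the members of this cluster differed in their ratios. Mir221 and Mir222, neighbours on the X chromosome, were both higher in replicate 2, at 1.01 and 1.65, and took 0.458% of the reads in replicate 1 and 1.01% in replicate 2. Mir21a (1518 and 4526 CPM), which is induced in reactive and inflamed tissue, was higher in replicate 2 by 1.58, and Mir674 (2974 and 6753 CPM) by 1.18.

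The miR-30 family, with 6 of 6 members detected, took 1.72 ± 0.210% of the reads, led by Mir30d (7412 ± 3.20 CPM), Mir30a (5485 ± 926 CPM) and Mir30e (3856 ± 1242 CPM). Gene families named Mir297, Mir466, Mir467 and Mir669, most of which lie in the rodent cluster within Sfmbt2, have 81 annotated genes, of which 8 were detected and 69 had no read in either library; 79 of the 81 share a stretch of 20 bases with another locus. Mir107 had 4191 and 13197 reads, while Mir103-1 had 8 and 16 and Mir103-2 had 33 and 109, so that all 3 were higher in replicate 2, at log2 ratios of 1.81, 1.15 and 1.87; Mir103-1 had too few reads to be tested.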
